A study of Mus musculus with 50 samples.

How the data were processed

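Polysome-associated RNA and total RNA of mouse NIH 3T3 fibroblast derivatives were each hybridised to Illumina bead arrays after amplification and biotin labelling, 50 arrays from 25 cultures. Per the labels, cells were treated with cycloheximide, polysomes were separated on sucrose gradients, and both RNAs were isolated with Tri Reagent after 4 h of treatment. The groups, the doses in µM, the replicate numbers and the 4 processing batches were taken from the labels. There were 3 replicates in every group except the non-inducible line without mifepristone, for which 1 culture was labelled. The labels do not state whether replicates were grown separately, so every p-value measures the spread among these cultures.

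The deposited non-normalized table gives, for 45281 probes, a linear intensity on each array and, per the file headers, a detection p-value for each intensity. The authors also deposited a processed table of log2 values, for which the normalization is not given in the sources used here. The ranks of the deposited log2 values within each array equalled those of the intensities (lowest Spearman correlation of an array 1.00), and their medians lay between 7.02 and 7.06. The platform table paired 34885 probes with 1 gene symbol and 18 with several, and it did not list 10378 probes. Of the probes with a symbol, 34807 were matched by gene ID to the mouse reference gene table, which was used for symbols and IDs only.

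Intensities were background-corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, using the detection p-values, with an offset of 16, and were quantile-normalized over all 50 arrays on the log2 scale. The probe with the highest mean stood for each of 19057 genes, and 12644 genes detected at p below 0.05 on at least 3 arrays were tested. Mean intensity ranged from 183 to 436 per array and the share of probes detected from 23.9% to 39.9%. The number of arrays limits the precision, and 95% intervals of fold changes are given for some of the comparisons where few or no genes passed.

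Translational efficiency was log2 polysome RNA (the fraction titled heavy) minus log2 total RNA of the same culture. Efficiency, polysome RNA and total RNA were each fitted over the 25 cultures with limma, with a term for each group and fixed terms for processing batch. All cultures with 4Ei-4 and of the non-inducible line were in batch 4, which held no other group, so comparisons that involve them against other groups used batch as a random block (duplicateCorrelation, statmod 1.5.0), with consensus correlations of 0.172 for efficiency, 0.448 for polysome RNA and 0.407 for total RNA. A gene is called where its Benjamini-Hochberg adjusted p over the 12644 genes was below 0.05, and every adjusted p of a gene is limma's. Values are log2 fold changes ± SE, and a gene's direction was counted over all pairs of cultures between the groups compared. The dose trend is the least-squares slope over the 5 group means, per 100 µM. For lists of genes, camera was run with a preset correlation of 0.01 and with an estimated correlation, and fry was run as an alternative. Of 26 lists, 25 had enough members to test, and p-values were adjusted over those 25 within each comparison and measure.

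The groups, comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. By that rule, Eif4e was named in every comparison. For the induction, 4Ei-1 at 200 µM, the dose trend, 4Ei-4, and 4Ei-1 against 4Ei-4, the rule took the 6 largest rises and 6 largest falls called in efficiency and the 4 largest each way in polysome and total RNA. For the other comparisons it took the 3 largest each way in efficiency. Named genes had to be detected on every array compared, and from each list that passed up to 4 members with the smallest adjusted p in the direction of the list were taken. Where no gene was called, the genes with the smallest p among those detected on every array compared are given as not passing. Unnamed predicted loci were passed over. Genes outside the rule are said to have been chosen after their values were seen.

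The fits were tested on simulated data with 12644 genes, 200 of them changed, and the spread of these arrays in total RNA and efficiency. Simulated polysome RNA was total RNA plus efficiency, so its variance was the sum of both and larger than the real one. In the real induction the median 95% half-width was 0.53 on polysomes against 0.67 in efficiency. The simulated shares for polysome RNA, recovered or of unchanged genes, therefore do not carry over to these arrays. For 4Ei-1 at 200 µM, 33% of genes changed by 1 on the log2 scale and 74% of those changed by 2 were recovered in efficiency, against 7% and 67% in polysome RNA and 54% and 95% in total RNA. For the induction these shares were 32% and 76%, 6% and 64%, and 61% and 93%. For mifepristone in the non-inducible line they were 7% and 53%, 2% and 24%, and 32% and 85%. In these fits at most 7.89% of calls were of unchanged genes. The simulated noise was independent between genes, with the same spread of a gene in every culture. Structure that genes share between the real cultures was therefore not tested, and the real error rate may be higher. With batch as a random block the error rate was not held in single fractions. For 4Ei-4 against no drug, 34.4% of calls in polysome RNA and 51.6% in total RNA were of unchanged genes, and for the line comparison 21.7% and 52.5%, against 7.19% in efficiency for each. The simulated batch effect was the same in both fractions of a culture and so cancelled in efficiency. The share in efficiency therefore does not show that the error rate is held there when batch acts on efficiency. For 4Ei-4 the recovered shares were 39% and 90% in efficiency, 0% and 21% in polysome RNA, and 6% and 38% in total RNA.

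Alternatives were the authors' log2 values, no background correction, quantile normalization within each fraction, no detection filter, all detected probes, no batch term, 1 batch alone, a replicate block, unpaired fractions, total RNA as a covariate, and omission of each culture. A filter for genes detected on every array compared, and a comparison of the lines within batch 4, were added after the data were seen. Relations across cultures were tested with 100000 permutations, and up to 100 regroupings of the cultures were fitted. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading and drawing. The length and folding of untranslated regions were not analysed here.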

Results

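RNA on polysomes and total RNA were measured in NIH 3T3 cells, a mouse fibroblast line, with an eIF4E gene inducible by the steroid mifepristone. A control derivative without induction was measured too. eIF4E binds the cap of mRNAs and starts their translation. The inducible line was grown without and with mifepristone. With mifepristone it also received the eIF4E inhibitor 4Ei-1 at 10, 50, 100 or 200 µM, or the less potent analog 4Ei-4 at 200 µM, for 4 h. Each of these groups had 3 cultures, as had the non-inducible line with mifepristone, and the non-inducible line without it had 1. The share of probes detected per array was 23.9% to 39.9%, and mean intensity was 183 to 436. The sample titles name the polysome fraction heavy, so lighter polysomes may have been left out. Translational efficiency is RNA of this fraction over total RNA of the same culture.

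The first comparison asks which mRNAs change in translation or amount when eIF4E is induced. Hes1 (gene ID 15205), a transcriptional repressor downstream of Notch, rose most on polysomes among the called genes detected on every array, by 3.08 ± 0.35 (adjusted p = 5.9e-05). Egr2 (gene ID 13654), an immediate early transcription factor, rose by 2.32 ± 0.34 (adjusted p = 0.00144). The next were Steap2 (gene ID 74051), a metalloreductase, at 2.14 ± 0.18 (adjusted p = 2.16e-06), and Phf13 (gene ID 230936), a chromatin reader, at 2.09 ± 0.23 (adjusted p = 5.9e-05). Each was higher with mifepristone in 9 of 9 pairs of cultures. The Notch target Hey1, named after its values were seen, was detected on 1 of 3 polysome arrays without mifepristone. By group means it was 8.90-fold higher, with values without mifepristone raised to at least the lowest signal detected on their array. That ratio has no batch term or interval. Within batches 1 and 3 the changes were 1.89 and 4.11 for Hes1, 1.94 and 3.12 for Egr2, 1.94 and 2.18 for Steap2, and 1.38 and 2.72 for Phf13. In total RNA Hes1 rose by 3.32 ± 0.32 (adjusted p = 9.24e-06) and the secreted kinase Pkdcc (gene ID 106522) by 2.55 ± 0.32 (adjusted p = 0.000268). Egr2 rose by 2.27 ± 0.41 (adjusted p = 0.00761) and Phf13 by 2.24 ± 0.23 (adjusted p = 2.91e-05), again in 9 of 9 pairs. Within batches 1 and 3 these were 2.47 and 4.27, 2.34 and 3.15, 1.82 and 3.27, and 1.79 and 2.73. Without the mifepristone culture of replicate 3, Egr2 was no longer called in polysome RNA (1.47, adjusted p = 0.163) or total RNA (1.19, adjusted p = 0.320).

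**Figure D1:**
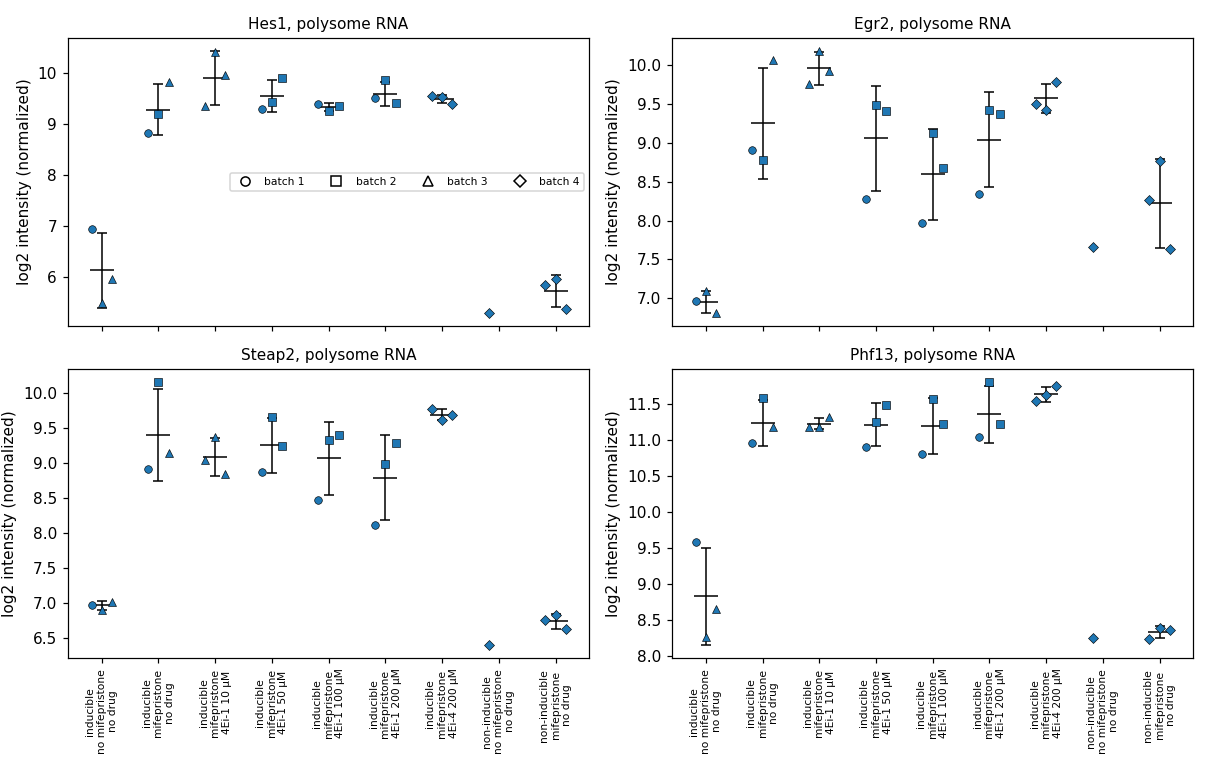
Normalised log2 polysome RNA of Hes1, Egr2, Steap2 and Phf13 in each culture (points, marker shape for the processing batch) of the 9 groups, with bars for the group mean and SD. All 4 genes lay higher in each inducible culture with mifepristone and no drug than in each without it (9 of 9 pairs), and Hes1 changed by 3.08.

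On polysomes 51 genes were called, 51 of them higher, and in total RNA 79, 73 higher and 6 lower. Of these, 34 rose in both fractions, and over the 96 genes called in either the median change in efficiency was 0.03. Genes lower in total RNA included the septin organiser Cdc42ep5 (-1.06 ± 0.19, adjusted p = 0.00761, higher in 0 of 9 pairs) and the nuclear pore protein Ndc1 (-1.02 ± 0.20, adjusted p = 0.0156, higher in 1 of 9). So were the Ral exchange factor Ralgds (-1.01 ± 0.21, adjusted p = 0.0275, higher in 0 of 9) and the histone demethylase Kdm4b (-0.93 ± 0.17, adjusted p = 0.00989, higher in 0 of 9). Within batches 1 and 3 they changed by -1.07 and -1.03, -1.39 and -0.90, -1.02 and -1.14, and -0.73 and -0.99. These 4 calls depended on single cultures. Without replicate 1 lacking mifepristone the adjusted p was 0.217 for Cdc42ep5, 0.420 for Ndc1, 0.236 for Ralgds and 0.169 for Kdm4b, and without mifepristone replicate 3 it was 0.0838, 0.0832, 0.241 and 0.135. Ndc1 and Ralgds also lost their call without mifepristone replicate 1 (0.0913 and 0.109) and replicate 3 lacking it (0.0523 and 0.0760), and Ralgds without replicate 2 lacking it (0.0875). Without replicate 1 of the cultures lacking mifepristone, the count on polysomes was 20 and in total RNA 27, and without replicate 2 of them the count on polysomes was 30. With no batch term 50 genes were called in total RNA and in batch 3 alone 31.

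As groups, the 8 mitochondrially encoded mRNAs had a median change of -1.23 on polysomes (1 of 8 up, and -1.13 and -1.41 within batches 1 and 3; camera adjusted p = 1.01e-05, and 0.342 with an estimated correlation). Adjusted over the list alone, 5 were lower, among them ND1 (-1.67, adjusted p = 0.111) and COX2 (-1.46, adjusted p = 0.142), both higher in 0 of 9 pairs. Ribosomal protein mRNAs had a median of 0.23 (44 of 54 up, 0.36 and 0.15 within batches; adjusted p = 3.37e-05, and 0.441 with an estimated correlation). With no batch term their mean changed sign to -0.05. Immediate early genes had a median of 0.40 (20 of 26 up, 0.51 and 0.41; adjusted p = 0.000127, and 0.342 with an estimated correlation). Of these 1 was called over all genes and 5 adjusted over the list alone, among them the transcription factors Klf4 (1.01, adjusted p = 0.0560) and Egr1 (1.29, adjusted p = 0.0808). Mitotic mRNAs had a median of -0.65 on polysomes (-1.36 and -0.06 within batches; adjusted p = 0.00016, and 0.441 with an estimated correlation). In total RNA they changed by -1.49 and 0.30 within batches 1 and 3. Extracellular matrix mRNAs had a median of -0.40 (-0.82 and -0.20; adjusted p = 0.00016, and 0.507 with an estimated correlation) and glycolytic mRNAs -0.24 (adjusted p = 0.000493, and 0.388). No list of the induction passed with an estimated correlation.

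In translational efficiency limma called 0 genes for the induction, with 558 at an unadjusted p under 0.05, and 0 under every alternative run except 1 omission. Without the mifepristone culture of replicate 3 it was 35. Among genes detected on every array compared, the 3 with the smallest p did not pass (adjusted p = 0.994). They were Plppr2 (1.18), the glycolipid anchor enzyme subunit Pigq (1.01, higher in 9 of 9 pairs) and the coatomer subunit Copb2 (-0.98, higher in 4 of 9). Half-widths of the 95% intervals had a median of 0.67, and 61.1% of genes had an interval within 1 of 0 on the log2 scale. Literature mRNAs sensitive to eIF4E, 25 of which were tested, moved by a median of 0.10 in efficiency (16 of 25 up, adjusted p = 0.490, and 0.673 with an estimated correlation), 0.09 on polysomes (20 of 25 up, adjusted p = 0.120, and 0.388) and 0.00 in total RNA.

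Eif4e itself (gene ID 13684) was called in no comparison by limma. For the induction it was detected on 4 of 12 arrays and changed by -0.90 ± 0.33 in efficiency (adjusted p = 0.994), -0.50 ± 0.26 on polysomes (adjusted p = 0.644) and 0.39 ± 0.20 in total RNA (adjusted p = 0.655). Its probe was near background, so these values do not show whether eIF4E was induced. With 4Ei-1 its efficiency changed by 0.83 ± 0.38 at 10 µM, 0.14 ± 0.33 at 50 µM, -0.38 ± 0.33 at 100 µM and 0.05 ± 0.33 at 200 µM, with a trend of -0.22 ± 0.17 per 100 µM. In efficiency it changed by 0.17 ± 0.36 with 4Ei-4 and by 0.00 ± 0.37 between the drugs. In the lines it changed by -0.65 ± 0.43 with mifepristone in the non-inducible line, by -0.25 ± 0.54 as the difference of the mifepristone effect between the lines, and by -0.28 ± 0.36 between the lines.

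The non-inducible line asks what mifepristone does without induction, with 1 culture lacking it as the reference, whose spread is assumed from the other groups. Interferon response mRNAs were higher on polysomes with mifepristone (median 0.43, 19 of 21 up; adjusted p = 3.08e-13, and 0.0225 with an estimated correlation). Among them were the guanylate-binding protein Gbp2 (1.46), the antiviral Ifit3 (1.09), Oasl2 (0.68) and the ISG15 protease Usp18 (0.55), each higher in 3 of 3 pairs and none called alone (adjusted p = 1.00). All 3 pairs share the 1 reference culture, so a low interferon state of that culture would give the same values. Mthfd2, a mitochondrial folate enzyme, changed by -2.27 ± 0.59 on polysomes and -2.24 ± 0.53 in total RNA without passing (adjusted p = 1.00). In total RNA, integrated stress response mRNAs (median -0.27; adjusted p = 1.41e-08, and 0.0515 with an estimated correlation) and glycolytic mRNAs (median -0.42; adjusted p = 6.47e-09, and 0.0515) passed with the preset correlation alone. For single genes limma called 0 genes in efficiency, polysome RNA and total RNA, with 35, 71 and 118 at an unadjusted p under 0.05. The authors' log2 values gave 5, 29 and 11 calls, and the replicate block gave 1 in each of polysome and total RNA. The median 95% half-width was 0.88 in efficiency, 0.69 on polysomes and 0.62 in total RNA. In efficiency the smallest p among genes detected on every array compared belonged to Babam2 (0.76), Zfyve26 (-0.88) and Ppie (0.80), none passing.

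The difference of the mifepristone effect between the lines asks which responses differ in cells with the inducible gene. On polysomes 5 genes were called, with larger rises in the inducible line, and in total RNA 4. With no batch term these were 0 and 2, and with the authors' log2 values 14 and 8, the latter sharing 2 genes in each. Together these were the Notch target repressors Hey1 and Hes1, Pkdcc, Steap2, the initiator caspase Casp9, the homeobox factor Dlx1 and the growth factor receptor Met, named after their values were seen. Over the 51 genes called on polysomes for the induction, the median change with mifepristone was 1.41 in the inducible line and 0.08 in the non-inducible line. In efficiency limma called 0 genes, with 152 at an unadjusted p under 0.05, and the authors' log2 values gave 3. Of genes detected on every array compared, Gbp2 (-1.26), Ppie (-1.29) and the mitochondrial chaperone Hspa9 (-1.10) had the smallest p, none passing.

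The next comparison asks which mRNAs 4Ei-1 at 200 µM changes in cells with induced eIF4E. Rcc1 (gene ID 100088), the exchange factor of the GTPase Ran, rose in efficiency by 1.59 ± 0.27 (adjusted p = 0.0266, 9 of 9 pairs higher), and Trmo (gene ID 74753), a tRNA methyltransferase, by 1.12 ± 0.22 (adjusted p = 0.0294, 9 of 9). Kctd1 (gene ID 106931), a transcriptional repressor, fell by 1.14 ± 0.23 (adjusted p = 0.0309, 0 of 9 pairs higher) and Shox2 (gene ID 20429), a homeobox factor, fell by 1.13 ± 0.25 (adjusted p = 0.0448, 0 of 9). Within batches 1 and 2 the changes were 1.76 and 1.35 for Rcc1, 1.14 and 1.18 for Trmo, -1.37 and -1.08 for Kctd1, and -1.19 and -1.10 for Shox2. In all, 51 genes were called in efficiency, 17 higher and 34 lower. These 4 were the ones detected on all 12 arrays. Tested among genes detected on every array, 1 stayed called. Without the drug-free replicate 2 all 4 lost their call, with an adjusted p of 0.0719 for Rcc1, 0.164 for Trmo, 0.156 for Kctd1 and 0.166 for Shox2. Without the drug-free replicate 1 it was 0.0926 for Trmo, 0.102 for Kctd1 and 0.127 for Shox2. Without replicate 2 with the drug it was 0.0503 for Trmo, and without replicates 1 and 3 with the drug 0.0648 and 0.0568 for Kctd1 and 0.0540 and 0.0864 for Shox2. The omission of the drug-free replicates 1, 2 and 3 gave 32, 9 and 93 calls, and of replicates 1 and 2 with the drug 122 and 92.

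On polysomes mitotic mRNAs had the largest group change with 200 µM, a median of 1.16 (19 of 19 up, 1.24 and 1.69 within batches 1 and 2; camera adjusted p = 9.21e-11, and 0.475 with an estimated correlation). None was called over all genes and 11 were when adjusted over the list alone. Its members included the mitotic kinases Plk1 (2.32 ± 0.71, adjusted p = 0.18), Aurka (1.64, adjusted p = 0.188) and Cdk1 (1.49, adjusted p = 0.243), and the anaphase activator Cdc20 (1.65, adjusted p = 0.222). DNA replication mRNAs had a median of 0.49 (23 of 28 up, 0.74 and 0.50 within batches; adjusted p = 5.29e-07, and 0.475 with an estimated correlation). Adjusted over the list alone 4 were called, among them the helicase subunits Mcm7 (1.30, adjusted p = 0.0966) and Mcm5 (1.73, adjusted p = 0.128). Integrated stress response mRNAs had a median of 0.20 (27 of 35 up, 0.56 and 0.18; adjusted p = 0.00483, and 0.475 with an estimated correlation), among them asparagine synthetase Asns (0.72, adjusted p = 0.128). Immediate early mRNAs had a median of -0.30 (3 of 26 up; adjusted p = 0.0156, and 0.585), but -0.65 within batch 1 and 0.11 within batch 2. In total RNA it was -0.22, with -0.59 and 0.08 within those batches. In total RNA mitotic mRNAs had a median of 0.89 (18 of 19 up, 1.01 and 0.97 within batches; adjusted p = 6.84e-08, and 0.536 with an estimated correlation). There DNA replication mRNAs had 0.36 (adjusted p = 8.54e-06, and 0.536) and cholesterol synthesis mRNAs 0.29 (adjusted p = 0.00316, and 0.536).

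**Figure D2:**
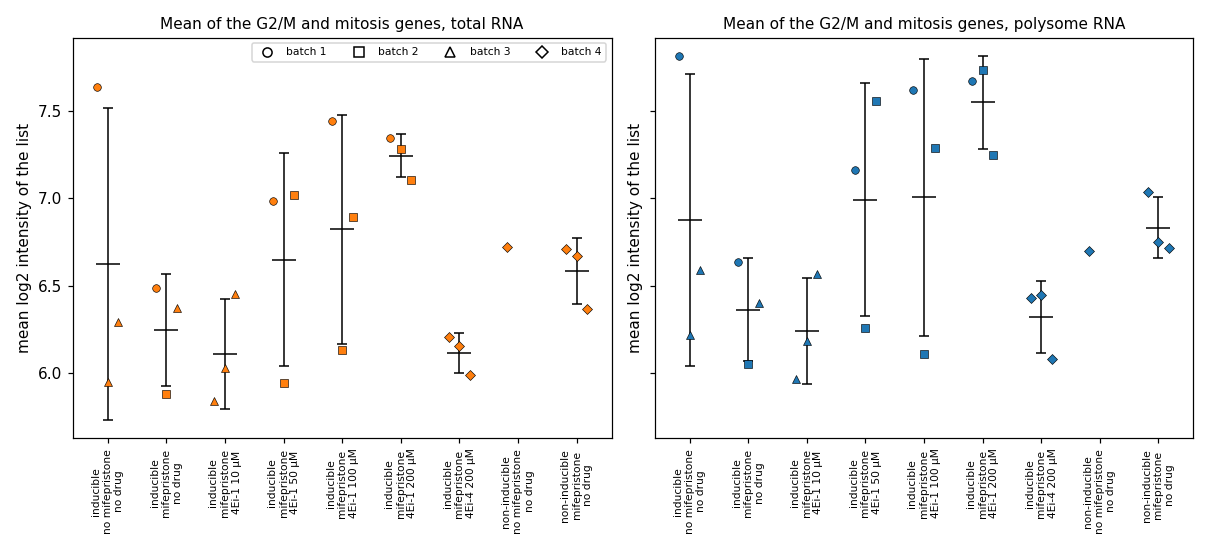
Mean normalised log2 level of the mitotic mRNAs in total and polysome RNA of each culture (points) by group, the bars giving the group mean and SD. In total RNA the cultures with 4Ei-1 at 200 µM lay between 7.11 and 7.35 and those with 4Ei-4 between 5.99 and 6.20, while the 6 drug-free inducible cultures spanned 5.88 to 7.64.

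On polysomes 2 genes were called at 200 µM, 1 higher and 1 lower, and in total RNA 24, 11 higher and 13 lower. The 1 of these detected on every array, Ebp, a sterol isomerase, fell by 0.98 ± 0.19 in total RNA (adjusted p = 0.0465, 0 of 9 pairs higher, -0.67 and -1.40 within batches 1 and 2). It was not called when genes detected on every array were tested alone. Its adjusted p was 0.0502 and 0.249 without drug-free replicates 1 and 2, and 0.0580 and 0.0975 without replicates 2 and 3 with the drug. Without drug-free replicates 1, 2 and 3 the count on polysomes was 1, 0 and 39, and in total RNA 40, 45 and 110. Without replicates 1, 2 and 3 with the drug it was 10, 61 and 14 on polysomes and 147, 35 and 34 in total RNA. In batch 2 alone the counts were 0 in efficiency, on polysomes and in total RNA. With the authors' log2 values the count in total RNA was 0, without background correction 3, with no batch term 2, with the replicate block 14 and among genes detected on every array 0. The literature list of eIF4E-sensitive mRNAs moved by a median of -0.15 in efficiency (10 of 25 up, -0.14 and -0.08 within batches 1 and 2; adjusted p = 0.555, and 0.806 with an estimated correlation). Other mRNAs with a 5 prime terminal oligopyrimidine tract moved by -0.20 (8 of 19 up; adjusted p = 0.523, and 0.806) and translation initiation factors by -0.13 (12 of 29 up; adjusted p = 0.523, and 0.806). No list passed in efficiency.

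The lower doses and the trend ask whether the response grows with 4Ei-1. At 100 µM Myo1c, an unconventional myosin, rose in efficiency by 1.12 ± 0.23 (adjusted p = 0.0343, 9 of 9 pairs, 1.19 and 1.11 within batches 1 and 2) and Kctd1 fell by 1.19 ± 0.23 (adjusted p = 0.0343, 0 of 9 pairs higher, -1.55 and -1.06). Without drug-free replicates 1 and 2 and 100 µM replicate 1 the adjusted p was 0.0981, 0.122 and 0.0550 for Myo1c and 0.0904, 0.122 and 0.0832 for Kctd1, and without 100 µM replicate 3 it was 0.0641 for Myo1c. Tested among genes detected on every array, neither was called. Across the 5 doses mitotic mRNAs on polysomes had a median slope of 0.53 per 100 µM (19 of 19 up; adjusted p = 3.25e-08, and 0.395 with an estimated correlation), with 7 called adjusted over the list alone. There immediate early mRNAs had a median slope of -0.19 (4 of 26 up; adjusted p = 0.000779, and 0.395). Immediate early mRNAs on polysomes also had a median of -0.37 at 50 µM (2 of 26 up, -0.56 and -0.08 within batches 1 and 2; adjusted p = 9.57e-05, and 0.245) and -0.44 at 100 µM (2 of 26 up, -0.76 and -0.13 within those batches; adjusted p = 5.02e-06, and 0.226), so the fall lay mostly in batch 1. On polysomes the genes with the smallest p of the trend, among those detected on every array compared, did not pass. They were Ets1 (-0.66 ± 0.11, adjusted p = 0.0520, 4 of 9 pairs of 200 and 0 µM higher), Arhgap24 (-0.51 ± 0.09, adjusted p = 0.0520, 1 of 9) and Wasl (-0.44 ± 0.08, adjusted p = 0.0578, 1 of 9).

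At 100 µM 40 genes were called in efficiency (14 higher), 12 on polysomes and 61 in total RNA, of which 2, 1 and 17 were detected on every array compared. Tested among such genes alone, 0, 1 and 4 were called. The replicate block gave 14, 3 and 19, no background correction 18, 0 and 17, and batch 2 alone 0, 0 and 0. At 50 µM the counts were 2, 0 and 20, and 792 genes on polysomes had an unadjusted p under 0.05. There the replicate block gave 0, 1 and 2, no background correction 0, 0 and 2, and batch 2 alone or genes detected on every array 0, 0 and 0. With 1 culture left out the counts at 100 µM ranged from 21 (drug-free replicate 2) to 168 (drug-free replicate 3) in efficiency, with 72 and 109 without 100 µM replicates 1 and 2. On polysomes they were 2 and 4 without drug-free replicates 1 and 2, and 24 and 66 without 100 µM replicates 1 and 2. In total RNA they were 121 without 100 µM replicate 1 and 181 without drug-free replicate 3. At 50 µM without drug-free replicates 1, 2 and 3 they were 34, 0 and 20 in efficiency, and without replicate 1, 2 and 3 with the drug 192, 0 and 5. In total RNA at 50 µM they were 66, 39 and 114 without drug-free replicates 1, 2 and 3, and 62 and 2 without 50 µM replicates 1 and 2. On polysomes they were 1 without drug-free replicate 1 and 143, 4 and 6 without 50 µM replicates 1, 2 and 3. With the authors' log2 values the calls at 100 µM were 13 in efficiency (4 of the 40 among them), 0 on polysomes and 2 in total RNA, and with no batch term 2, 4 and 0. At 50 µM total RNA gave 0 with the authors' log2 values. At 10 µM limma called 0 genes in efficiency, on polysomes and in total RNA, with 125, 136 and 161 at an unadjusted p under 0.05, and 0 under every alternative run. Among genes detected on every array compared, the smallest p in efficiency belonged to Plscr4 (0.78), the phosphatase Ppp5c (0.69) and the adaptor Crk (-0.67), none passing (adjusted p = 1.00). The trend called 3 genes in efficiency, 0 on polysomes (1498 at an unadjusted p under 0.05) and 5 in total RNA, none detected on every array, and with no batch term it called 887, 1474 and 8. With 1 culture left out it called 0 to 46 in efficiency, 0 to 43 on polysomes (43 without 50 µM replicate 1) and 1 to 65 in total RNA (65 without 200 µM replicate 1).

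4Ei-4 at 200 µM was included to probe effects of the drug other than on eIF4E. Its cultures shared no batch with the drug-free cultures, so no within-batch value exists. Rpl7a (gene ID 27176), a ribosomal protein of the large subunit, fell in total RNA by 1.58 ± 0.22 (adjusted p = 0.00668, 0 of 9 pairs higher), and it stayed called with each of 6 cultures left out. In efficiency 1 gene was called, the propionyl-CoA carboxylase subunit Pcca (2.47 ± 0.40, adjusted p = 0.0426). It was not detected on every array and was named after its values were seen. With any culture left out, 0 genes were called in efficiency. On polysomes limma called 0 genes, with 322 at an unadjusted p under 0.05, against 5 with the authors' log2 values, 2 with no detection filter and 13 with no batch term. There Cyp2f2 (1.87), Ly6e (1.71) and Olfml2b (1.86) had the smallest p among genes detected on every array compared, none passing. Extracellular matrix mRNAs had a median change of 0.78 on polysomes (29 of 31 up; adjusted p = 9.19e-08, and 0.657 with an estimated correlation) and 0.65 in efficiency (27 of 31 up; adjusted p = 5.63e-05, and 0.538). Members included the protease inhibitor Timp1 (0.81 on polysomes), the laminin chain Lamc1 (1.28) and the protease Mmp2 (0.91), none called. The mean efficiency of the matrix list spanned -1.56 to 0.01 in the drug-free cultures with mifepristone and -0.52 to 0.08 with 4Ei-4, so the groups overlapped. Ribosomal protein mRNAs had a median of 0.26 in efficiency (44 of 54 up; adjusted p = 5.63e-05, and 0.501), and the eIF4E-sensitive list had -0.20 (6 of 25 up; adjusted p = 0.175, and 0.501). In simulated data of this comparison 51.6% of calls in total RNA were of unchanged genes.

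The next comparison is between the drugs at the matched dose of 200 µM. No batch held both drugs, so drug and batch cannot be told apart here. Total RNA fits with a random batch block did not hold the error rate in the simulated comparisons, and this one was not simulated. Rpl7a was higher in total RNA with 4Ei-1 than with 4Ei-4 by 1.60 ± 0.23 (95% interval 1.12 to 2.07, adjusted p = 0.00777, 9 of 9 pairs), the 1 gene called between the drugs. In total RNA 4 genes were called without 4Ei-1 replicate 1, 3 without its replicate 2, 9 with the authors' log2 values and 76 with no batch term, Rpl7a among them each time. Mitotic mRNAs had a median difference of 1.01 in total RNA (19 of 19 up; adjusted p = 1.15e-09, and 0.189 with an estimated correlation) and 1.19 on polysomes (18 of 19 up; adjusted p = 4.21e-08, and 0.560). Immediate early mRNAs had a median difference of -0.54 in total RNA (adjusted p = 8.86e-06, and 0.189) and extracellular matrix mRNAs -0.66 on polysomes (adjusted p = 1.14e-06, and 0.570). In efficiency limma called 0 genes, with 732 at an unadjusted p under 0.05, and 5 with the authors' log2 values. Among genes detected on every array compared, 3 are given by smallest p, with adjusted p of 0.284, 0.284 and 0.542. They were the proteoglycan Sdc4 (-1.79 ± 0.35, interval -2.51 to -1.07), Acad10 (-1.65 ± 0.33, interval -2.32 to -0.97) and Pcca (-1.73 ± 0.41, interval -2.58 to -0.88). On polysomes limma called 0, with 793 at an unadjusted p under 0.05, against 5 with the authors' log2 values, 9 with no detection filter and 365 with no batch term. There Snhg18 (1.40), Zcchc9 (1.36) and Ly6e (-1.60) had the smallest p among genes detected on every array compared, none passing. The median 95% half-width was 0.77 in efficiency, 0.84 on polysomes and 0.71 in total RNA, and 42.95%, 32.3% and 54.3% of genes had an interval within 1 of 0. The eIF4E-sensitive list differed by a median of 0.04 in efficiency (adjusted p = 0.938, and 0.946 with an estimated correlation).

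The last comparison sets the inducible against the non-inducible line, both with mifepristone and no drug. No batch held both groups. Inflammatory and interferon mRNAs were lower in the inducible line. NF-kappaB targets had a median of -1.35 on polysomes (adjusted p = 1.55e-09, and 0.00315 with an estimated correlation; 5 called, 12 adjusted over the list alone). They had -1.45 in total RNA (adjusted p = 1.51e-10, and 0.00663; 11 called, 12 adjusted over the list alone). Interferon mRNAs had -1.01 on polysomes (1 of 21 up; adjusted p = 2.47e-11, and 0.0124; 6 called, 10 adjusted over the list alone), and -0.84 in total RNA (adjusted p = 1.28e-07, and 0.0762). Within batch 4, where the inducible cultures had 4Ei-4, the list means were -1.05 on polysomes and -1.27 in total RNA for NF-kappaB targets and -0.93 and -0.97 for interferon mRNAs. On polysomes the chemokine Cxcl1 differed by -5.46 ± 1.01 (adjusted p = 0.00331), Gbp2 by -3.19 ± 0.58 (adjusted p = 0.00302), the interferon regulatory factor Irf1 by -2.73 ± 0.48 (adjusted p = 0.00211) and the superoxide dismutase Sod2 by -2.45 ± 0.32 (adjusted p = 7.72e-05), all in 0 of 9 pairs higher. In total RNA the chemokine Ccl2 differed by -4.30 ± 0.58 (adjusted p = 8.56e-05), the adhesion molecule Vcam1 by -2.67 (adjusted p = 0.00083) and the glycolytic enzyme Pgk1 by -2.80 (adjusted p = 0.000319). The cytochrome subunit Cyc1 was higher by 1.15 (adjusted p = 0.00596, 9 of 9 pairs).

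Between the lines 325 genes were called on polysomes (149 higher in the inducible line) and 789 in total RNA (366 higher), with 52.5% of calls in total RNA and 21.7% on polysomes of unchanged genes in simulated data of this comparison. The simulated noise of polysome RNA was wider than that of these arrays. Among genes detected on every array 57 and 284 were called, with no batch term 1413 and 2062, and within batch 4, where the inducible cultures had 4Ei-4, 5989 and 5442. Without drug-free inducible replicates 1 and 2 and non-inducible replicate 1 the count on polysomes was 192, 196 and 202. In total RNA it was 457, 456 and 1665 without drug-free inducible replicates 1, 2 and 3, and 478 without non-inducible replicate 2. In efficiency limma called 0 genes, with 1020 at an unadjusted p under 0.05, against 64 with the authors' log2 values, 17 with no background correction, and 12 without the drug-free inducible replicate 3. Of genes detected on every array compared, Tmem259 (1.70 ± 0.32, adjusted p = 0.114), the chromatin factor Ing3 (-1.34, adjusted p = 0.242) and Kank1 (1.15, adjusted p = 0.301) had the smallest p. Extracellular matrix mRNAs had a median difference of 0.84 in efficiency (27 of 31 up; adjusted p = 1.44e-06, and 0.857 with an estimated correlation), among them the collagen Col4a2 (2.53, adjusted p = 0.464). Their mean efficiency spanned -1.56 to 0.01 in the inducible cultures and -1.93 to -1.65 in the non-inducible ones.

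Efficiency of extracellular matrix mRNAs varied between cultures of 1 group. Relations to other mRNAs were chosen for testing after this was seen, those with secretory mRNAs and array brightness before their own values were. As deviations from group means over 24 cultures, it followed the efficiency of 54 other secretory pathway mRNAs (Pearson r = 0.976, Spearman rho = 0.980, permutation p = 1e-05 for both, the smallest the permutations can give, adjusted p = 6e-05 over 6 relations). Without the 2 cultures farthest from the median r was 0.970, and with batch removed as well as group it was 0.976. With 35 mRNAs of cytosolic complexes r was 0.0231 (rho 0.0278, permutation p = 0.936), and with ribosomal protein mRNAs -0.737 (rho -0.705, permutation p = 0.00384, adjusted p = 0.0115). With long non-coding RNAs it was -0.648 (rho -0.636, permutation p = 0.0110, adjusted p = 0.0220). Within batches the matrix list ranged over 1.77, 1.44, 0.51 and 2.01 on the log2 scale in batches 1, 2, 3 and 4. Cultures of 1 group in 1 batch differed by 1.40 for 100 µM in batch 2, and by 0.054 to 0.61 in the other 6 groups with several cultures in a batch. At 200 µM of 4Ei-1 its median change in efficiency was 1.13 within batch 1 and -1.01 within batch 2.

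**Figure D3:**
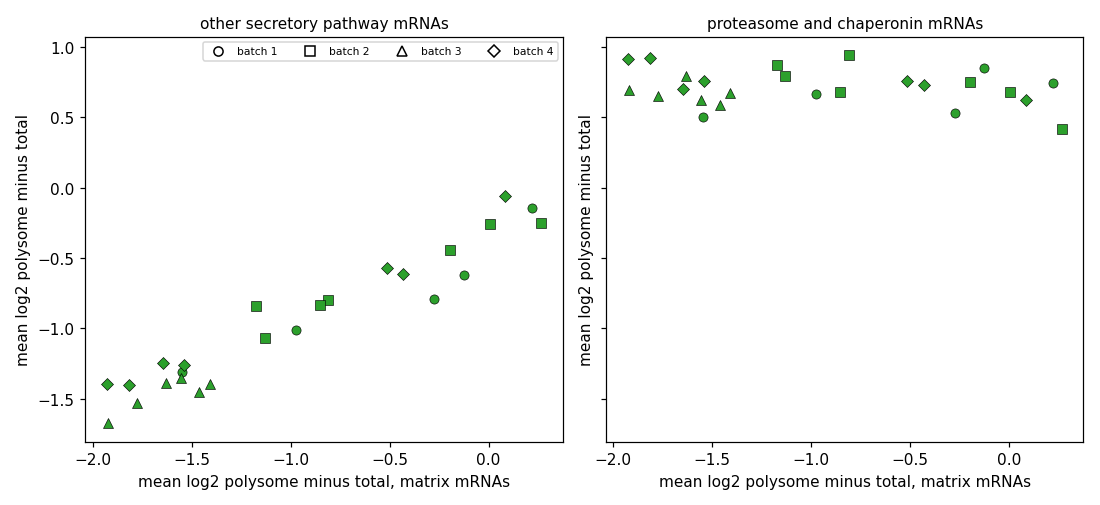
Mean efficiency (log2 polysome minus total RNA) in each of 25 cultures (points, marker shape for the batch), with the extracellular matrix list on the horizontal axis and other secretory mRNAs (left) or proteasome and chaperonin mRNAs (right) on the vertical axis. Deviations from group means gave r = 0.976 on the left and 0.0231 on the right.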

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

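The tests of explanations in this part were chosen after the result was seen. For 7 genes the effect of mifepristone differed between the inducible and the non-inducible line by an interaction test. On polysomes the difference was 3.22 ± 0.38 for Hey1 (adjusted p = 0.000986), 3.15 ± 0.51 for Pkdcc (adjusted p = 0.0335), 1.82 ± 0.32 for Casp9 (adjusted p = 0.0491), 1.81 ± 0.30 for Steap2 (adjusted p = 0.0379) and 1.80 ± 0.32 for Dlx1 (adjusted p = 0.0491). In total RNA it was 3.07 ± 0.53 for Hes1 (adjusted p = 0.0410), 3.04 ± 0.29 for Hey1 (adjusted p = 4.3e-05), 2.38 ± 0.33 for Met (adjusted p = 0.00342) and 1.89 ± 0.23 for Steap2 (adjusted p = 0.000941). Hey1 and Met were detected on 0 of 3 total RNA arrays of the inducible line without mifepristone. On polysomes Hey1 and Pkdcc were detected on 1 of 3 such arrays. Values on these arrays were raised to at least the lowest signal detected on each. By group means Hey1 and Met were then 7.34-fold and 5.001-fold higher with mifepristone in total RNA. Hey1 and Pkdcc were 8.90-fold and 6.61-fold higher on polysomes. These ratios have no batch term and no allowance for sampling error, so they are not lower bounds of the effect. The non-inducible reference was 1 culture, assumed to vary like the other groups, so an unusual state of that culture would give the same differences. With no batch term 0 genes were called on polysomes and 2 in total RNA. The authors' values gave 14 (2 of the 5 among them) and 8 (2 of the 4), the replicate block 1 and 5, and genes detected on every array 0 and 5. With 1 culture left out, the count of 5 on polysomes was 2, 3 and 2 without the inducible mifepristone replicates 1, 2 and 3, 1 without replicate 2 or 3 lacking mifepristone, and 1 without any of the 3 non-inducible mifepristone cultures. In total RNA the count of 4 was 2 without the inducible mifepristone replicate 3, and 7 without its replicate 2 or without replicate 1 lacking mifepristone.

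The pattern behind these genes is the rise of 51 genes on polysomes with mifepristone in the inducible line. Processing batch is argued against by the 38 genes called higher in batch 3 alone. In batch 1, which had no part in choosing them, their median change was 1.25 (38 of 38 higher, 1 culture against 1). Cultures of 1 group in 1 batch differed in them by a median of at most 0.22. An action of mifepristone itself, alike in both lines, is argued against as the whole cause. The 51 genes had a median of 0.0751 in the non-inducible line, against 1.41 in the inducible line. They were chosen by their rise in the inducible line, so selection raises the 1.41 but not the 0.0751. The 1 non-inducible culture without mifepristone limits the comparison: single cultures elsewhere departed from the others of their group by a median of up to 0.20 in these genes. Dependence on the cap binding that 4Ei-1 inhibits stays open. The 38 genes held 106.8% of their batch 1 induction at 200 µM (83.03% to 124.1% by pair of cultures), but the list of eIF4E-sensitive mRNAs did not show that the drug acted (median -0.15 in efficiency, adjusted p = 0.806 with an estimated correlation). The regulator protein through which mifepristone induces the gene may act on these genes without eIF4E. It stays open and untested beside eIF4E itself, since the labels do not state whether the non-inducible line carries the regulator.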

How the results depend on the processing

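A filter for genes detected on every array and a comparison within batch 4 were chosen after seeing the data. The count of 51 genes higher on polysomes with induction was between 36 and 63 under every alternative on all its cultures or batch 3 alone, and with 1 culture left out between 20 and 55. The genes changed more than the count: 27 of the 51 were among the 45 called in batch 3 alone, and 12 among the 46 called without mifepristone replicate 3. In total RNA 30 of the 79 were among the 82 called without that replicate. The replicate block gave 37, although cultures sharing a replicate number were not alike (median r 0.050 on polysomes). For the changes that follow the cause was not tested, except that 1 batch alone holds fewer cultures.

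In efficiency the count of 51 at 200 µM was 12 with the authors' values (5 of the 51 among them), 14 without background correction (8), 20 with no batch term (15), 0 in batch 2 alone, 25 unpaired (22), 23 with total RNA as covariate (8) and 1 among genes detected on every array, and 9 to 122 with 1 culture left out. The block gave 21 for them and 1 for the trend and the lines. The count of 3 for the trend was 1 with the authors' values (none of the 3), 0 without background correction, unpaired or among genes detected on every array, 13 with no filter, 887 with no batch term (1 of the 3 among them), and 0 to 46. The 1 call of 4Ei-4 became 0 with normalization within fractions, no filter, all probes, unpaired, covariate, detection on every array or any culture left out, and with the authors' values the 1 call was another gene. The authors' values gave 5 calls between the drugs, 3 for the difference between the lines in mifepristone effect, 5 for the non-inducible line and 64 between the lines. The lines also gave 17 without background correction, 1 normalized within fractions, 7 with no filter, 6 with all probes, 5 with no batch term, 6 with covariate, 4319 within batch 4, and 0 to 12. The induction gave 0 throughout, and 0 to 35 with 1 culture left out (35 without mifepristone replicate 3).

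On polysomes the count of 2 at 200 µM was 0 with the authors' values, in batch 2 alone or with detection on every array, 7 without background correction, 27 with no filter, 11 with all probes, 9 with no batch term, and 0 to 61. A paired block called 2, of which 1 was among them. The counts of 325 and 789 between the lines were 57 on polysomes and 284 in total RNA with detection on every array, 1413 and 2062 with no batch term, and 5989 and 5442 within batch 4.

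List means reversed in 15 cases. With no batch term they were 0.15 for matrix mRNAs at 50 µM on polysomes, -0.12 for ribosomal mRNAs in the polysome trend and -0.0544 in the induction. In batch 2 alone they were 0.0678 for matrix mRNAs at 100 µM in total RNA, and for immediate early mRNAs at 200 µM 0.10 on polysomes and 0.10 in total RNA. In batch 3 alone, and equally without replicate 1 lacking mifepristone, the induction gave 0.12 for DNA replication on polysomes and 0.25 for mitosis in total RNA. With 1 culture left out DNA replication ranged from -0.63 to 0.12 and mitosis from -1.18 to 0.25. Matrix mRNAs ranged from -0.48 to 0.14 at 50 µM on polysomes (highest without 50 µM replicate 1), and in total RNA from -0.37 to 0.0697 against 4Ei-4 and from -0.22 to 0.0737 in the trend (both highest without 200 µM replicate 1). Oxidative phosphorylation in efficiency with 4Ei-4 ranged from -0.0025 (without drug-free replicate 2) to 0.26. The covariate gave -0.0690 for glycolysis in the non-inducible line. With an estimated correlation 4 list calls held and 126 were lost, and with fry 8 held.

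Of 33 counts, the number that moved by over 1.5 times was 23 with the authors' values, 20 with no batch term, 14 with the replicate block, 14 with detection on every array, 13 without background correction, 13 with all probes, 12 with no filter and 3 with normalization within fractions. The alternative for untranslated regions was not run. Detection differed between the counts: 4 of the 51 genes called in efficiency at 200 µM, and 43 of the 51 on polysomes for the induction, were detected on every array.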

Other observations

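The tests of explanations in this part were chosen after the results were seen, except those of secretory mRNAs and of array brightness for the matrix list, written before their own values were seen. So was the contrast of the fractions. Over all 25 cultures 6789 of 12644 genes differed between polysome and total RNA, 4052 higher and 2737 lower on polysomes. The fractions were quantile-normalized together, so this balance depends on that scaling. The polysome fraction was titled heavy, so a low value need not mean absence from lighter polysomes. The highest included mRNAs of the transcription factor Sox4 (2.35 ± 0.14), the translational repressor Samd4b (2.23) and cyclin Ccnd2 (2.00). The lowest included the spliceosomal RNA Rnu6 (-2.76), the amino acid transporter Slc38a2 (-2.50), the small nucleolar host RNA Snhg12 (-2.49), ribosomal Rpl39 (-2.38) and fibronectin Fn1 (-2.30).

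As groups, mRNAs of initiation factors (median 0.48, 21 of 29 higher; adjusted p = 0.112 with an estimated correlation) and of DNA replication (0.49, 20 of 28 higher; 0.112) lay towards polysomes. Ribosomal protein mRNAs (-0.87, 46 of 54 lower; 0.112), long non-coding RNAs (-1.23, 8 of 8 lower; 0.112), mitochondrially encoded mRNAs (-1.91; 0.154) and matrix mRNAs (-0.92, 28 of 31 lower; 0.425) lay away from them. The literature list of eIF4E-sensitive mRNAs had a median of 0.01. None of these lists passed with an estimated correlation.

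Matrix mRNAs varied in efficiency between cultures of 1 group. Processing batch stays open: of the sum of squares within groups 66.3% was left after batch was removed (47.1% to 82.5% with 1 culture left out). Batch means were -0.54, -0.56, -1.63 and -1.11, a range of 1.09. Of 7 groups with several cultures in 1 batch, the range was 1.40 for 100 µM in batch 2 and 0.054 to 0.61 for the other 6. The brightness of the polysome array against the total RNA array stays open. Its correlation was -0.0645, but -0.328 with batch removed as well as group, so a bound of 0.3 on the first value alone was too narrow a test. Uneven recovery of polysomes bound to the endoplasmic reticulum is a candidate explanation: the other secretory mRNAs moved along with r = 0.976 and mRNAs of cytosolic complexes with r = 0.0231. The change was not confined to secretory mRNAs, since ribosomal protein mRNAs (r = -0.737) and long non-coding RNAs (r = -0.648, adjusted p = 0.0220) moved the opposite way. No biological explanation was tested, so a shared regulation of secretory translation stays open.

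With batch as a term, mitotic mRNAs were higher with 4Ei-1 at 200 µM than in the drug-free cultures with mifepristone, without passing with an estimated correlation. In total RNA the 6 drug-free inducible cultures, with or without mifepristone, spanned 5.88 to 7.64. That range enclosed the 7.11 to 7.35 of the cultures at 200 µM. Growth state falling along the doses by chance stays open: an exact permutation of the doses within batches 1 and 2 (11 cultures, 15120 arrangements) gave p = 0.0158 for a slope of 0.51 per 100 µM, and 0.389 adjusted over 25 lists. Low mitotic mRNAs in the shared drug-free cultures may contribute: against cultures with neither mifepristone nor drug the list was higher by a mean of 0.50 (17 of 19 up, camera p = 0.270 with an estimated correlation), less than against the shared controls. Only batch 1 held both of these groups, with 1 culture each, so that mean rests largely on the batch terms. There, in total RNA, Cdc20 changed by -1.73 with mifepristone and by 0.91 from that with 200 µM. The values were -1.50 and 1.07 for Cenpa, -1.99 and 1.78 for Anln, and -1.63 and 1.69 for Birc5. Of these only Birc5 thus ended above the culture without mifepristone. An effect of 4Ei-1 on the cell cycle stays open as the biological explanation.

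Other splits of the same cultures were fitted for each count. For groups of 3 against 3 there are 10 splits, too few for a share under 0.05, and 9 could be fitted for the induction. For the induction the real count and the highest of the others were 0 and 0 in efficiency (9 of 9 as large), 51 and 1 on polysomes (1 of 9) and 79 and 1 in total RNA (1 of 9). At 10 µM 10 of 10 splits were as large as the real count of 0 in each measure, with up to 1 call. At 50 µM the real and highest counts were 2 and 572 in efficiency (6 of 10 as large), 0 and 817 on polysomes (10 of 10) and 20 and 113 in total RNA (3 of 10). Calls several times the real count point to a structure of the samples. The split with 817 calls followed batch 2. Within batch 2 the drug called 0, which says little, since 1 of its cultures there was drug-free. At 100 µM they were 40 and 58 (2 of 10), 12 and 81 (3 of 10) and 61 and 91 (3 of 10), and at 200 µM 51 and 53 (2 of 10), 2 and 58 (7 of 10) and 24 and 114 (6 of 10). Of 100 regroupings drawn for the dose trend, 36 gave as many as the 3 calls in efficiency (highest 1078), 100 as many as the 0 on polysomes (highest 1513) and 36 as many as the 5 in total RNA (highest 312), so chance is not excluded, and counts that high point to a structure of the samples. For 4Ei-4 they were 1 and 0 (1 of 10), 0 and 0 (10 of 10) and 1 and 0 (1 of 10), and between the drugs 0 and 0 (10 of 10), 0 and 0 (10 of 10) and 1 and 0 (1 of 10). Between the lines they were 0 and 0 (10 of 10), 325 and 0 (1 of 10) and 789 and 0 (1 of 10). In this comparison and those with 4Ei-4, only the real split set batch 4 against the other batches. A batch difference alone could therefore give a higher real count, and these splits do not bear on line or drug.

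Fold changes in efficiency of the induction and of 200 µM 4Ei-1 had a correlation across genes of -0.313, where genes are not independent replicates. The shared controls alone gave -0.289 on average (-0.305 to -0.276) in 20 simulations, so the real value lay beyond each of them. On polysomes it was -0.271 against a simulated -0.293 (-0.313 to -0.276), and in total RNA -0.255 against -0.291 (-0.318 to -0.273), in both less negative than in any simulation. The covariances were more negative than in every simulation in all measures: -0.0513 in efficiency (simulated -0.0419 to -0.0365), -0.0350 on polysomes (-0.0274 to -0.0236) and -0.0269 in total RNA (-0.0220 to -0.0186). So r and covariance pointed the same way in efficiency and opposite ways in the fractions. The simulated noise was independent between genes, while genes of the real cultures share structure, so the simulated ranges are too narrow. A real value outside them therefore does not show a reversal. Whether the induction is reversed beyond the shared controls stays open. Of the 51 genes called in efficiency at 200 µM, 13 were called in the same direction at 100 µM, against the same drug-free cultures. No 2 arrays of 48 pairs compared shared more than 0.786% of their values.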
